A study of Mus musculus with 38 samples.

How the data were processed

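The series holds nuclear RNA-seq of the adult mouse cortex. Nuclei of 4 neuron types were tagged by a Cre-dependent nuclear envelope protein fused to GFP (Sun1/sfGFP) and pulled down, and each type was taken from male mice aged 8 to 10 weeks whose Mecp2 label was WT or KO. L4 and L5 name excitatory neurons of cortical layers 4 and 5 (Nr5a1-Cre and Rbp4-Cre), and PV and SST name inhibitory interneurons that make parvalbumin or somatostatin (Pvalb-Cre and Sst-Cre). The 38 samples are 32 sorted libraries, 4 per cell type and label, and 6 input libraries of unsorted nuclei (by label 3 PV KO, 1 PV WT, 1 L5 KO and 1 L5 WT). The deposited column of 1 input labelled PV KO is named as WT. Per the labels, RNA was extracted with a column kit and libraries were made with the Ovation SoLo kit.

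The values used are raw counts of reads in the exons of 34193 genes, 1 table per cell type, as deposited by the authors, with duplicate reads kept. The submitters' processing notes list Trim Galore, Bowtie, STAR, bedtools and DESeq2 and the genome build mm9; their versions and roles are not given in the sources used here, nor is the handling of strand. The deposited tables also give each gene's coordinates and summed exon length in base pairs, and these set gene length (start to end) and the positions printed here. A second set of deposited tables holds the authors' own DESeq2 comparisons of KO with WT, from which the log2 fold change without shrinkage and the adjusted p-value of each gene were read, for a count of calls only. Count columns were matched to samples by animal number or index; 2 count columns of the L5 table match no sample and were left out, and 74 other columns of values per library were not read. Gene types came from the GENCODE vM21 annotation by symbol (28376 symbols matched, 19117 of them protein-coding).

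Each KO against WT comparison was fitted on the 8 sorted libraries of 1 cell type with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after its low-count filter and TMM scaling, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Differences between cell types in the KO effect were fitted as interaction terms over genes tested in each type involved. WT libraries were compared between L4 and L5 and between PV and SST, and sorted PV KO libraries with the inputs labelled PV KO. Genes called at 4-fold or more between the WT libraries of a pair formed a set that was tested in the KO comparisons of the other pair, with camera in limma 3.58.1 and a correlation between genes of 0.01, and again with an estimated correlation. The 31 gene lists were tested in the same way, adjusted over the lists within each cell type. Genes over 100 kb were compared with all other tested genes by the mean log2 CPM (counts scaled to a common library total, prior count 2) of each library, with a two-sided exact permutation test over 70 arrangements, which cannot give a p below 0.0286. The comparisons, gene lists, tests and most alternatives were fixed before the data were examined.

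Genes are named by a rule fixed at the same time. In each KO comparison these are the genes called, with a mean of at least 2 CPM and every KO library on one side of every WT library, that have the 8 largest log2 fold changes up and the 8 largest down, plus up to 4 called members of each list with the smallest adjusted p. For each interaction they are the 5 largest differences in each direction, and for the WT and input comparisons the marker lists and the 5 largest changes in each direction. For genes called in 3 or more cell types, up to 15 are named. Predicted genes are counted and passed over for the next gene.

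The number in a library's pull-down label was tested as a pairing. Across genes, residuals of KO and WT libraries with the same number correlated at 0.24 to 0.36 in L4 and 0.252 to 0.582 in L5, in 4 of 4 pairs each, at −0.054 to 0.223 in PV and at 0.043 to 0.352 in SST. In L5 the numbers are those of the sample titles; the deposited column names number WT 1 and 2 the other way, and the pairs this gives correlated at −0.058 and −0.24. Values from a fit with this number as a block therefore stand beside those of L4 and L5, and the genes named from it follow the same rule, applied to that fit after the data were seen. For SST, where 3 of 4 pairs correlated at over 0.1, the count of calls and the result for PV markers in that fit are given too. The share of long genes among the higher genes of that fit is given for PV and SST as well. The alternatives were the scaling of DESeq2 inside edgeR, no low-count filter, DESeq2 1.42.0 with the same filter, limma on log2(TPM + 1) computed from the deposited counts and exon lengths, an FDR of 0.1, the block, each library left out in turn, other length limits, and sets at 2-fold. The tests were tried on simulated data with the same depth and spread per gene, drawn without any structure of replicate numbers. A true log2 change of 1 was called in 78 to 84% of genes in L4, PV and SST and in 54 to 56% in L5. Between 7 and 18 unchanged genes were called per comparison, in each type a share above 0.05 of the calls. In PV the 18 stood beside 41 and 39 of 50 genes changed by 1 and −1, and 17 and 14 of 50 changed by 0.5 and −0.5. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.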

Results

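Nuclear RNA was counted in sorted nuclei of 4 cortical neuron types from mice labelled Mecp2 WT or KO. MeCP2 binds methylated DNA, and the title of the series points to long genes whose expression differs between similar neurons. Each type had 4 libraries per label. The total count per library was 3453726 to 5232618 in L4 KO and 4277253 to 5873998 in L4 WT. It was 5317786 to 12938097 in L5 KO and 5283625 to 11979789 in L5 WT. In PV it was 5317678 to 7361999 in KO and 6473931 to 10135425 in WT, and in SST 7066977 to 10333454 in KO and 7620538 to 10220269 in WT. The 6 input libraries had 5606936 to 8804602. Mitochondrial transcripts made up 0.0554 to 0.3005% of the counts of sorted libraries and 1.20 to 2.61% of those of inputs. Below, CPM are given as mean ± SD over 4 libraries, and log2 fold changes of KO against WT as value ± SE of the fit with 4 libraries against 4. Adjusted p-values are those of edgeR unless another tool is named.

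Counts of Mecp2 (chromosome X, 71271931 to 71331029) fell in sorted SST and PV nuclei of the libraries labelled KO but remained well above 0. In SST they went from 207 ± 9.62 CPM in WT to 85.03 ± 19.84 CPM in KO (log2 −1.27 ± 0.13, adjusted p = 2.12e-04). In PV they went from 164 ± 14.96 to 107 ± 23.0 CPM (−0.63 ± 0.13, adjusted p = 0.0354). In L4 the counts were 152 ± 24.1 CPM in KO and 160 ± 9.78 CPM in WT (−0.05 ± 0.12, adjusted p = 0.970). In L5 the KO libraries parted: KO 1 and 3 had 171 and 211 CPM and KO 2 and 4 had 54.5 and 68.7 CPM, beside 159 to 190 CPM in WT (−0.43 ± 0.37, adjusted p = 1.00). The counts cover all exons of the gene together. Irak1, which encodes an interleukin receptor kinase and lies next to Mecp2 (71259253 to 71269257), was higher in every KO library than in every WT library of the same type. Its mean went from 37.6 ± 4.37 to 119 ± 15.7 CPM in L4 and from 39.1 ± 5.88 to 103 ± 16.9 CPM in L5. It went from 51.5 ± 6.27 to 87.1 ± 7.71 CPM in PV and from 50.7 ± 5.69 to 94.9 ± 7.93 CPM in SST.

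**Figure D1:**
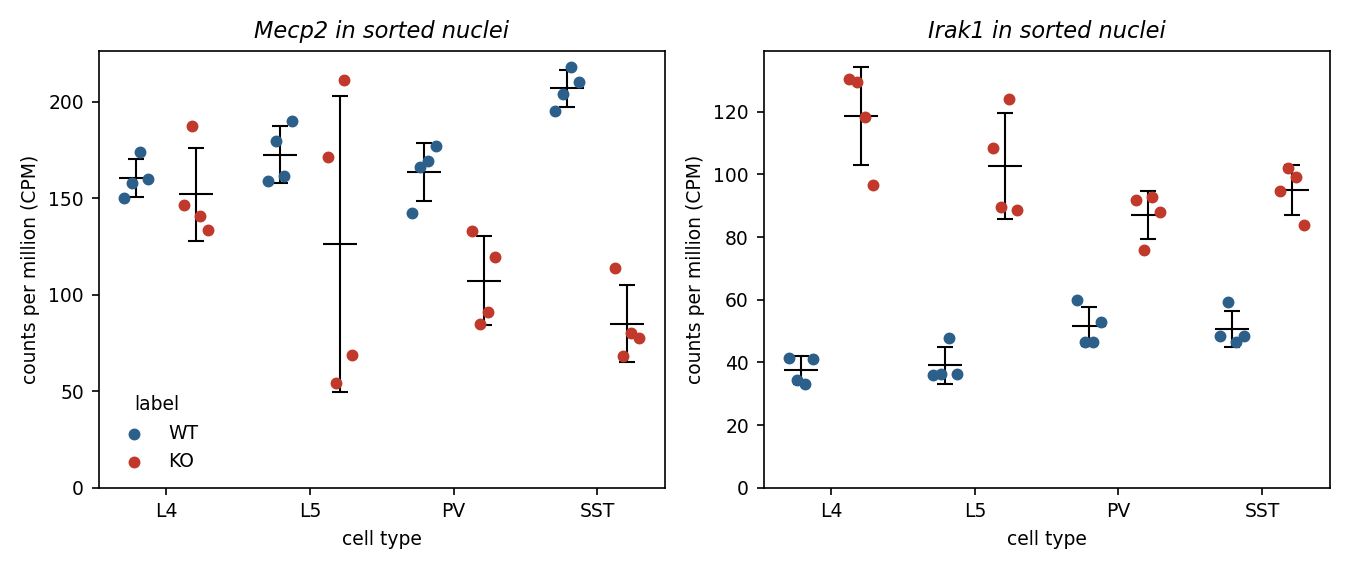
CPM of Mecp2 (left) and Irak1 (right) in each sorted library, by cell type and label, with 1 point per library and the mean ± SD of 4 libraries. Mecp2 is lower in KO in PV and SST and overlaps WT in L4 and in L5 KO 1 and 3, whereas Irak1 in KO (76.0 to 130 CPM) lies above WT (33.2 to 59.8 CPM) in all 4 types.

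In L4 neurons, KO against WT asks how excitatory neurons of layer 4 respond to the Mecp2 label. Predicted genes aside, the largest rise after Irak1 was that of Col5a1 (chromosome 2, 27741945 to 27895034), a fibrillar collagen gene, which went from 49.5 ± 12.4 to 116 ± 27.5 CPM (1.25 ± 0.18, adjusted p = 0.0122). The BMP receptor gene Bmpr1b (0.98 ± 0.18), the complement protease gene Masp1 (0.75 ± 0.14), the transcription factor genes Maf (0.74 ± 0.14) and Tshz1 (0.60 ± 0.11), the receptor phosphatase gene Ptprt (0.68 ± 0.12), Enpp2 (0.59 ± 0.10), which encodes autotaxin, and the teneurin gene Odz3 (0.59 ± 0.09) also rose. Scn7a (chromosome 2, 66511482 to 66622971), of the sodium channel family, fell most, from 28.2 ± 1.65 to 7.40 ± 2.10 CPM (−1.91 ± 0.18, adjusted p = 1.10e-04). The T-type calcium channel gene Cacna1h fell by 1.32 and the sodium channel subunit gene Scn3b by 1.14 on the log2 scale. Olfr78, Ccdc3, the Wnt antagonist gene Frzb, Echdc2, Rab26 and the guidance receptor gene Robo3 fell by 0.66 to 1.31.

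Of 12462 genes tested in L4, 11 were called higher and 12 lower in KO, and with the replicate number as a block 86 were higher and 113 lower, among them all 23. In 497 genes (3.99%) the KO and WT libraries did not overlap, where chance gives 2.86%. The block added rises in Hs3st4 (1.04), the transcription factor gene Runx2 (0.78, block adjusted p = 4.20e-04) and Zfp516 (0.75), and falls in Syt6, Postn, Cyp11a1, the growth regulator gene Stc1, Lgr5 and Bub1b (−1.32 to −1.52). Without 1 library the count of 23 was 6 (KO 1), 8 (KO 3), 5 (KO 4), 13 (WT 1), 8 (WT 3) or 4 (WT 4), and with DESeq2 it was 58.

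Of the 31 gene lists, 7 were called lower in L4 KO, and none of these calls held with an estimated correlation between genes, where the adjusted p was 0.842 for each. Sodium and calcium channel genes had 2 of 30 measured members lower (Scn3b and Cacna1h) and 4 when adjusted over the list alone (list adjusted p = 0.0420). Ribosomal protein genes (76 measured, mean log2 −0.12, adjusted p = 0.00764), oxidative phosphorylation genes (73, −0.10, adjusted p = 0.0123) and heat shock genes (14, −0.18, adjusted p = 0.0129) had no member called. Markers of some other cells were lower: oligodendrocyte markers (11 of 11 negative, mean −0.36, adjusted p = 0.00103), oligodendrocyte precursor markers (4 of 4 negative, −0.77, adjusted p = 0.00215, 2 lower when adjusted over the list alone) and SST markers (7 of 7 negative, −0.47, adjusted p = 0.0452). Astrocyte markers leaned the other way (8 of 11 positive, 0.15, adjusted p = 0.105) and were called higher with the block (adjusted p = 0.0433). So were synaptic adhesion genes (adjusted p = 0.0433), while inhibitory markers (0.00782), neuropeptide genes (0.0154), activity genes (0.0415) and VIP markers (0.0415) were called lower, and no adjusted p was below 0.05 with an estimated correlation. Synaptic adhesion genes had 1 of 60 members higher (Odz3), or 4 higher and 1 lower when adjusted over the list alone, and 5 higher and 1 lower with the block (Ntng2 at 0.54 and Odz2 at 0.39 higher, Ptprf at −0.61 lower).

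In L5 neurons, which lie below layer 4 and send axons out of the cortex, 3 genes were called, of which Irak1 and Scn7a were also called in L4. Irak1 rose (1.40 ± 0.17, adjusted p = 0.0299). Scn7a fell from 61.2 ± 4.64 to 23.2 ± 4.33 CPM (−1.39 ± 0.15, adjusted p = 0.0149). Afap1l1, which encodes an actin-associated protein (chromosome 18, 61889915 to 61946356), rose from 19.4 ± 1.46 to 38.9 ± 4.42 CPM (1.01 ± 0.13, adjusted p = 0.0432). In all, 14203 genes were tested. With the replicate number of the sample titles as a block 97 genes were higher and 97 lower, but with WT 1 and 2 numbered as in the deposited column names 2 genes were called in all, so the genes that follow rest on the numbers of the titles. Among the genes higher in that fit were Col5a1 (19.8 ± 5.66 to 57.7 ± 16.7 CPM, log2 1.54, block adjusted p = 6.45e-07), Fam43a, Hpse, which encodes heparanase, the receptor gene Notch2, the potassium channel gene Kcns1 and Mical1 (0.92 to 1.41). Pappa2 fell by 2.81, and Dnahc7b, an axonemal dynein gene, Postn, the growth factor family gene Fgf11, Adamts1, Olfr78 and the retinoic acid-degrading enzyme gene Cyp26b1 fell by 1.26 to 1.74.

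Among the lists in the blocked L5 fit, axon guidance genes had 3 members higher and 1 lower (Sema5a at 0.89, Unc5d at 0.51 and Slit1 at 0.48 higher, Efnb3 at −0.84 lower). Synaptic adhesion genes had 4 higher and 1 lower (Sdk1 at 0.66, Lphn2 at 0.43, Odz3 at 0.40), and sodium and calcium channel genes 3 lower (Cacna1g at −0.88, Scn9a at −0.86, Scn3b at −0.60). In the fit without block, oxidative phosphorylation genes (73 of 75 positive, mean 0.17, adjusted p = 2.66e-06) and ribosomal protein genes (61 of 76 positive, 0.14, adjusted p = 4.82e-04) were shifted up and chromatin and methylation genes (39, −0.08, adjusted p = 0.0113) and oligodendrocyte precursor markers (6 of 6 negative, −0.53, adjusted p = 8.17e-04) down, none with a member called. With an estimated correlation the adjusted p was 0.896 for ribosomal protein genes and 0.857 for the other 3 lists. With the block PV markers were shifted up too (6 of 9 positive, 0.23, adjusted p = 0.0407, or 0.892 with an estimated correlation).

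The L5 libraries fell into 2 sets that cross the labels, replicates 1 and 3 (totals of 5283625 to 7409621) and replicates 2 and 4 (9979344 to 12938097). The numbering of the column names pairs KO 1 with WT 2 and KO 2 with WT 1, across these sets. Within replicates 1 and 3, edgeR called 23 genes, 21 higher and 2 lower, with Irak1 at 1.48 ± 0.18 (adjusted p = 0.0127). Within replicates 2 and 4 it called 0, with 507 genes at an unadjusted p under 0.05, DESeq2 called 6, and Irak1 was at 1.30 ± 0.14 (adjusted p = 0.137). Over all 8 libraries 555 genes had an unadjusted p under 0.05, 399 (2.81%) had KO and WT libraries that did not overlap, where chance gives 2.86%, and DESeq2 called 50. The count of 3 was 3 without WT 3, 1 without KO 2 and 0 without any other single library, where 421 to 652 genes had an unadjusted p under 0.05 and DESeq2 called 17 to 46.

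PV interneurons fire fast and inhibit the cell bodies of other neurons, and in them the largest rises included protease, integrin and collagen genes. Capn11, a calpain protease gene, went from 0.613 ± 0.399 to 4.95 ± 2.35 CPM (2.87 ± 0.48, adjusted p = 0.00808). The integrin gene Itga8 (1.75 ± 0.32), the ephrin receptor gene Epha8 (1.74 ± 0.30), the collagen genes Col5a1 (1.57 ± 0.20) and Col4a1 (1.23 ± 0.15), the nicotinic receptor gene Chrna4 (1.36 ± 0.14), the AMPA receptor auxiliary subunit gene Gsg1l (1.29 ± 0.13) and the GDNF receptor gene Gfra1 (1.16 ± 0.14) followed. Fgf11 (chromosome 11, 69609570 to 69615359) fell from 37.4 ± 5.37 to 11.4 ± 1.53 CPM (−1.73 ± 0.13, adjusted p = 2.09e-05). The serotonin receptor gene Htr4, Cyp2s1, the ryanodine receptor gene Ryr1, Dnahc7b, the tropomyosin gene Tpm2, the kinase gene Wnk4 and Dgka, a diacylglycerol kinase gene, fell by 1.00 to 1.62.

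Of 12967 genes tested in PV, 75 were called higher and 34 lower, and 930 (7.17%) had KO and WT libraries that did not overlap, where chance gives 2.86%. Synaptic adhesion genes had 8 of 61 members higher and 0 lower, or 13 higher and 2 lower when adjusted over the list alone (list adjusted p = 6.00e-04): Sdk1 (1.04 ± 0.11), Flrt3 (0.82 ± 0.09), Dscam (0.79 ± 0.10) and Odz3 (0.75 ± 0.08) were among them. Axon guidance genes had 4 higher and 1 lower of 50, or 6 and 1 when adjusted over the list alone (list adjusted p = 0.00178), with Slit1 at 0.83 ± 0.14, Sema5a at 0.58 ± 0.12 and Epha10 at −0.66 ± 0.09. Oxidative phosphorylation genes (70 of 73 positive, mean 0.25, adjusted p = 1.40e-14, 2 higher when adjusted over the list alone) and ribosomal protein genes (58 of 68 positive, 0.21, adjusted p = 5.50e-04) were shifted up with no member called, and astrocyte markers (11 of 11 negative, −0.45, adjusted p = 0.0234) down. With an estimated correlation the adjusted p was 0.767 for each of these 5 lists. Some genes with many near-identical copies have low counts in the PV table, such as Rpl10 at 7.90 CPM in PV WT and 60.5 CPM in SST WT. Tuba1c went the other way, at 10.05 CPM in PV WT and 0.355 CPM in SST WT.

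Other PV genes named from the lists included receptor and channel genes. The metabotropic glutamate receptor gene Grm1 (chromosome 10, 10405857 to 10802154) rose from 61.0 ± 5.25 to 124 ± 5.06 CPM (1.00 ± 0.09, adjusted p = 5.16e-05), and Grin2d fell by 0.47, the 2 of 24 glutamate receptor genes called (6 higher and 6 lower when adjusted over the list alone). The potassium channel genes Kcnb2 (0.87 ± 0.12) and Kcnh5 (0.84 ± 0.10), the calcium channel subunit gene Cacna2d3 (0.79 ± 0.17), the cadherin gene Cdh13 (0.73 ± 0.10), Crhbp (0.59 ± 0.11), Lmo3 (0.55 ± 0.11) and the glucocorticoid-responsive gene Fkbp5 (0.94 ± 0.19) rose. The serotonin receptor gene Htr1f (−0.90 ± 0.18) and the calcium channel subunit gene Cacnb3 (−0.83 ± 0.12) fell. The count of 109 was 66 without KO 3, 72 without KO 4, and 71, 68 and 64 without WT 1, 2 and 3. DESeq2 called 259 genes.

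SST interneurons had the most genes called, 185 higher and 77 lower of 13989 tested. With the replicate number as a block 455 were higher and 270 lower, although 1 of the 4 pairs of numbers correlated at only 0.043. The imprinted Notch ligand family gene Dlk1 (chromosome 12, 110691033 to 110701546) rose from 10.8 ± 4.77 to 31.0 ± 4.79 CPM (1.52 ± 0.23, adjusted p = 0.00291). So did the actin-binding protein genes Nexn (1.51 ± 0.21) and Tns1 (1.34 ± 0.25), the adhesion gene Sdk1 (1.34 ± 0.15), the G protein gene Gna14 (1.27 ± 0.30), the transcription factor genes Foxc1 (1.26 ± 0.30) and Tshz2 (1.05 ± 0.11) and Bicc1 (1.06 ± 0.24), which encodes an RNA-binding protein. Receptor genes were among the falls: the neuropeptide receptor gene Npbwr1 fell from 4.09 ± 0.799 to 1.02 ± 0.483 CPM (−1.94 ± 0.32, adjusted p = 0.00498) and the bombesin-family receptor gene Grpr by 1.51. Lower too were Snai2, a transcription factor gene, the collagen gene Col11a2, Ccdc108, Irs4, Gdpd2 and Scn7a (−1.42 to −1.70). In 1160 genes (8.29%) the KO and WT libraries did not overlap, where chance gives 2.86%.

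Synaptic adhesion genes had 9 of 61 members higher and 1 lower in SST KO, or 13 and 3 when adjusted over the list alone (list adjusted p = 8.24e-07), among them Odz3 (185 ± 25.9 to 375 ± 29.97 CPM, 1.03 ± 0.11), Flrt3 (1.02 ± 0.12) and Ntng1 (0.88 ± 0.11). Axon guidance genes had 6 of 52 higher and 1 lower, or 20 and 5 when adjusted over the list alone (list adjusted p = 8.24e-07), with Slit1 (0.69 ± 0.10), Slit3 (0.67 ± 0.12) and Efna5 (0.56 ± 0.08) higher and Efnb3 (−1.08 ± 0.12) lower. Cadherin genes had 6 of 25 higher and 1 lower, or 8 and 1 when adjusted over the list alone (list adjusted p = 0.0399), with Cdh22 (0.68 ± 0.15), Cdh4 (0.59 ± 0.10), Pcdh9 (0.55 ± 0.08) and Cdh13 (0.42 ± 0.09). Potassium channel genes had 2 of 59 higher, or 12 higher and 1 lower when adjusted over the list alone (list adjusted p = 0.0399), with Kcnh5 (0.74 ± 0.09) and Kcnab2 (0.44 ± 0.10). With an estimated correlation the adjusted p of these 4 lists was 0.762, 0.624, 0.872 and 0.830.

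In SST KO the marker lists called were those of PV, excitatory and L4 neurons. PV markers had 3 of 12 members higher, Pvalb (22.9 ± 4.31 to 37.5 ± 5.33 CPM, 0.72 ± 0.14), Syt2 (0.59 ± 0.14) and Mybpc1 (0.97 ± 0.23), with a list adjusted p of 0.0399. With the replicate number as a block the PV marker list was not called (adjusted p = 0.0752). Excitatory markers (10 of 10 positive, mean 0.33, adjusted p = 0.0195, 3 called when adjusted over the list alone) and L4 markers (6 of 6 positive, 0.27, adjusted p = 0.0188, Cux1 called at 0.44 ± 0.09) were shifted up, as were glucocorticoid targets (11 of 12 positive, 0.21, adjusted p = 0.0399, none called). With an estimated correlation the adjusted p was 0.624, 0.863, 0.580 and 0.624. Not called were markers of VIP neurons (4 of 10 positive, mean −0.14, adjusted p = 0.0723), L5 neurons (10 of 13 positive, 0.14, adjusted p = 0.205), astrocytes (10 of 11 positive, 0.28, adjusted p = 0.141) and oligodendrocytes (11 of 12 positive, 0.19, adjusted p = 0.181). The sodium and calcium channel genes Cacna1g (155 ± 16.5 to 70.8 ± 22.8 CPM, −1.12 ± 0.17), Scn3b (−0.82 ± 0.08) and Scn9a (−0.70 ± 0.12) fell, as did the opioid receptor gene Oprm1 (−1.05 ± 0.16), Crh (−1.14 ± 0.15), which encodes corticotropin-releasing hormone, Npr3 (−0.82 ± 0.17), Flna (−0.77 ± 0.17) and Igfbp3 (−0.66 ± 0.14). Hdac9 (0.52 ± 0.10), Grik4 (0.53 ± 0.13) and Grid1 (0.44 ± 0.10) rose. The count of 262 was 156 without KO 2 and 145, 128, 107 and 124 without WT 1, 2, 3 and 4. DESeq2 called 426 genes.

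Long genes are the subject of the title, and genes over 100 kb were frequent among the genes higher in KO. They made up 48 of 75 higher genes in PV (64.0%) and 127 of 185 in SST (68.6%), against 15.5% and 15.2% of tested genes, and 10 of 34 (29.4%) and 11 of 77 (14.3%) of the lower ones. With the block they were 57 of 86 (66.3%) in L4 and 46 of 97 (47.4%) in L5 (by the numbers of the titles), against 15.75% and 14.98% of tested genes, and without it 5 of 11 and 0 of 2. The median length of the higher genes was 143 kb in PV and 175 kb in SST. Long genes as a whole passed the test in no type: their mean log2 CPM relative to other genes differed between KO and WT by 0.07 in L4 (exact permutation p = 0.257), 0.01 in L5 (p = 0.886), −0.0004 in PV (p = 1.00) and 0.11 in SST (p = 0.0857), with adjusted p of 0.514, 1.00, 1.00 and 0.343 over the 4 tests. The sign of the L5 difference turned without KO 1 (−0.0238), KO 3 (−0.0331), WT 2 (−0.019) or WT 4 (−0.0405), and that of the PV difference without KO 2 (0.0119), KO 3 (0.0308) or WT 3 (0.025). In SST it was 0.15 without WT 1 (exact permutation p = 0.0286), the 1 library whose absence put it past 0.05. Between libraries of the same number it was positive in 4 of 4 SST pairs (0.0973 to 0.1293). It was positive in 3 of 4 pairs in L4 and in 2 of 4 in L5 and in PV. So few pairs cannot pass 0.05 in an exact sign-flip test. Taken singly, 63.8% of long genes were higher in L4 KO, against 46.9% of other genes. The shares were 64.6% and 47.4% in SST, 51.4% and 50.8% in L5, and 45.6% and 50.4% in PV. These shares were not tested.

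**Figure D2:**
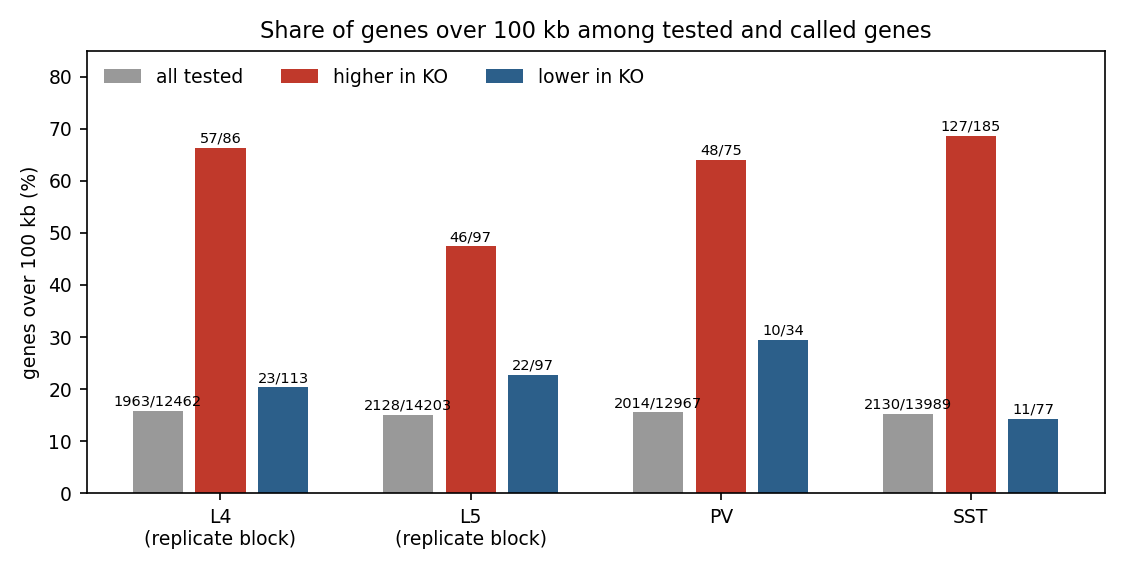
Percent of genes over 100 kb among all tested genes, genes called higher in KO and genes called lower in KO, for each cell type, with the number of long genes over the number of genes above each bar. L4 and L5 are from the fit with the replicate number as a block. The share among higher genes is 66.3% in L4, 47.4% in L5, 64.0% in PV and 68.6% in SST, against 14.98 to 15.75% of tested genes.

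Several genes changed in more than 1 cell type, always in the same direction. Irak1 was called in all 4 types, Tshz1 (0.60 to 0.98), Col5a1 (0.82 to 1.57) and Odz3 (0.59 to 1.03) were higher in L4, PV and SST, and Scn7a was lower in L4, L5 and SST. In total 37 genes were higher and 10 lower in 2 or more types, and 0 were called in opposite directions. PV and SST shared 36 higher genes where 1.05 would be expected, and 8 lower genes where 0.149 would be expected. Irak1 is among the 37 and the 36, and Mecp2 itself among the 10 and the 8. Without these 2 genes PV and SST shared 35 higher and 7 lower genes. With the blocked fits of L4 and L5, 75 were higher and 40 lower in 2 or more types, and Irak1, Tshz1, Col5a1, Odz3, the cadherin-related gene Fat1 and Aff1 were higher in all 4.

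**Figure D3:**
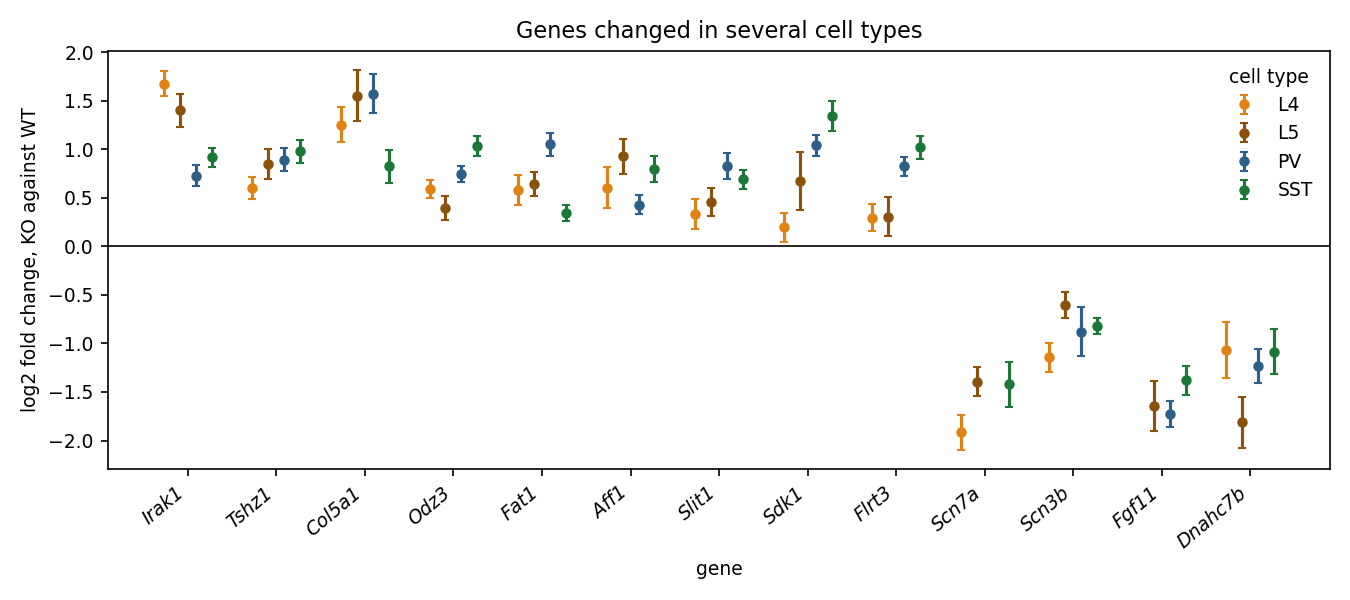
Log2 fold change of KO against WT for 13 genes in each of the 4 cell types, with bars of ± 1 SE from fits of 4 libraries against 4. Irak1 lies between 0.73 and 1.68, Col5a1 lies between 0.82 and 1.57, and Scn7a between −1.39 and −1.91 where it was tested.

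The size of the KO effect was compared between types. Between PV and SST, 4 of 12819 genes differed, all with the higher effect in PV: Grm1 (PV 1.00 ± 0.09, SST −0.16 ± 0.09, difference 1.17 ± 0.12, adjusted p = 2.48e-05), Chrna4 (1.36 ± 0.14 and 0.29 ± 0.11, adjusted p = 0.0260), Galnt14, a glycosyltransferase gene (1.14 ± 0.14 and 0.28 ± 0.09, adjusted p = 0.0383), and Gm10828, a predicted gene chosen after its values were seen (1.22). Between the excitatory and the inhibitory types, 12 of 11941 genes differed, 11 with the lower effect in the excitatory types (145 with the block, 115 of them lower). Gsg1l differed by −1.17 ± 0.17 (adjusted p = 0.00114), the signalling protein gene Shh by −1.15 ± 0.23, the glycogen phosphorylase gene Pygm by −1.06 ± 0.19, B3gat1 by −0.92 ± 0.16 and the laminin gene Lamb1 by −0.82 ± 0.17. Irak1 had the higher effect in the excitatory types (0.71 ± 0.13, adjusted p = 0.0127). Between L4 and L5, edgeR called 0 of 12426 genes, with 200 at an unadjusted p under 0.05, and DESeq2, limma and the block gave 0. The count for PV and SST was 2 without PV KO 3, PV KO 4, PV WT 1, SST KO 1, SST KO 4 or SST WT 3, and that for excitatory and inhibitory types 20 without L4 KO 3 or L5 WT 2.

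**Figure D4:**
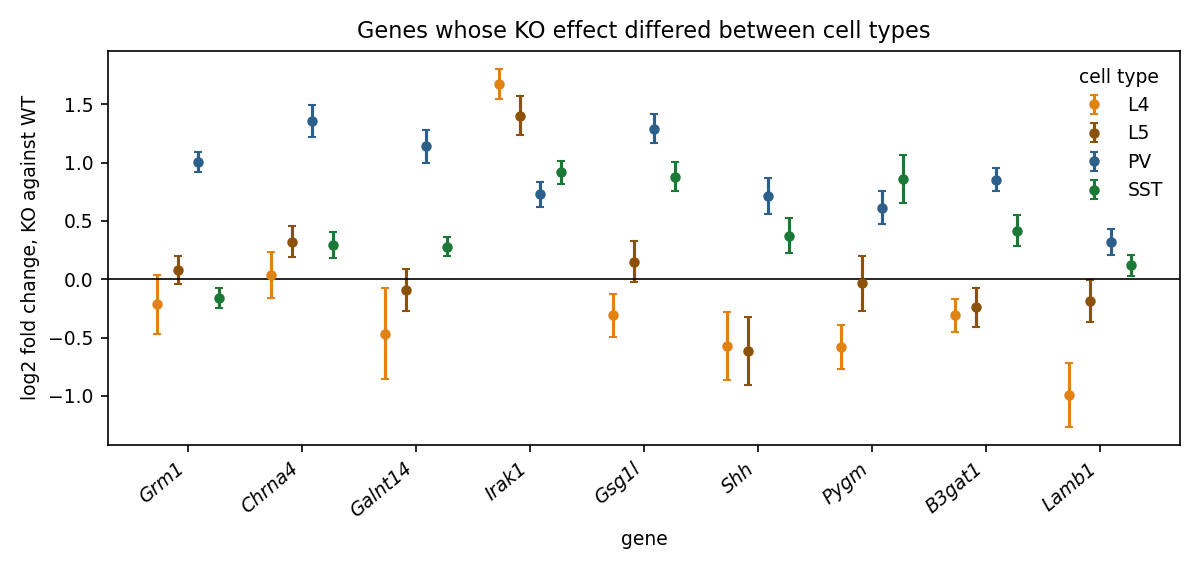
Log2 fold change of KO against WT in each cell type for 9 genes whose KO effect differed between types, with bars of ± 1 SE from fits of 4 libraries against 4. Grm1, Chrna4 and Galnt14 are higher in PV than in SST, and the other genes differ between the excitatory (L4, L5) and the inhibitory types.

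Among WT libraries, each sorted type carried its own markers. L4 markers were higher in L4 than in L5 for 9 of 10 genes, with Rspo1 at 3.40 ± 0.33 and Tmem215 at 3.12 ± 0.15, and Nr5a1 was at 18.4 ± 4.52 CPM in L4 and 0.0811 ± 0.0962 CPM in L5. L5 markers were lower in L4 for 12 of 13. Sstr4, a somatostatin receptor gene (−4.29 ± 0.21), Rxfp2, Pde6c, Sim1 and Adam18 differed most towards L5. Nr5a1, Cd200r4 and Cyp39a1 differed most towards L4. Of 13215 genes, 874 were higher in L4 and 1281 in L5. PV markers were higher in PV than in SST for 10 of 12 genes, with Mybpc1 at 4.52 ± 0.17, Syt2 at 3.82 ± 0.15 and Kcng4 at 4.10 ± 0.16. SST markers were lower for 13 of 13, with Chodl at 23.4 ± 3.79 CPM in SST and 0.0992 ± 0.1252 CPM in PV. Of 13731 genes, 3463 were higher in PV and 3580 in SST. Cell type goes with Cre line and deposited table, and 68 of 76 ribosomal protein genes were lower in PV (mean −2.01), so the differences of Rpl9, snoZ39, SNORA27 and Tuba1c, 4 of the 10 named there, cannot be told apart from a difference in how the tables were made. The remaining large differences included Adamtsl5 towards PV (4.20 ± 0.19) and Myh13 towards SST.

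Genes that distinguish a pair of types included many long ones. Of 267 genes called at 4-fold or more between L4 and L5, 28.5% were over 100 kb, against 15.5% of tested genes, and of 642 between PV and SST 21.3%, against 15.4%. The 380 PV-SST genes tested in L4 were lower in L4 KO than other genes by 0.12 on the log2 scale (camera p = 8.39e-04, adjusted p = 0.00336), but the camera p was 0.280 with an estimated correlation. Without L4 KO 2 or L4 WT 3 the difference was −0.08 or −0.07 and no longer past the unadjusted threshold of 0.05. The set takes in genes whose PV-SST difference cannot be told apart from how the tables were made, such as Rpl9. It also takes in SST markers. As lists, ribosomal protein genes and SST markers were themselves lower in L4 KO (mean −0.12 and −0.47). The 512 PV-SST genes tested in L5 differed by −0.05 in L5 KO (adjusted p = 0.252), and the L4-L5 genes by 0.10 in PV KO (adjusted p = 0.373) and 0.04 in SST KO (adjusted p = 0.196). With protein-coding members only and without ribosomal protein genes, the difference in L5 was larger and past the unadjusted threshold. The difference in PV was 0.172 and past that threshold without PV KO 1, and −0.0423 without PV KO 4. Also past it were that in SST without SST KO 1 (0.0804) or SST WT 2 (0.176) and that in L5 without L5 WT 3 (−0.0731). For members over 100 kb alone the difference was 0.0909 in PV KO and 0.101 in SST KO, both past the unadjusted threshold. For those up to 100 kb it was 0.105 in PV KO and 0.016 in SST KO, neither past it, and in L4 KO the shorter PV-SST genes were past it (−0.135) and the longer not (−0.072). Each part was compared with all other tested genes of any length, so length was not held fixed. Long genes as a whole differed by 0.11 in SST KO and −0.0004 in PV KO. Called in KO were 4 higher and 5 lower of 166 L4-L5 genes in PV and 8 higher and 7 lower of 216 in SST. These made up 8.26% of called genes in PV and 5.73% in SST, against 1.28% and 1.54% of tested genes. PV-SST genes made up 17.4% of the 23 genes called in L4 and 33.3% of the 3 in L5, against 3.05% and 3.61% of tested genes. Camera tests a shift of the mean, in which changes in both directions can cancel. The shares themselves were not tested.

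Sorted PV KO nuclei were compared with the 3 inputs labelled PV KO to describe the sort. In 1 of these inputs, whose deposited column is named as WT, Mecp2 (174 CPM) and Irak1 (40.4 CPM) stood at the WT level, against 38.5 and 100 CPM of Mecp2 and 98.9 and 114 CPM of Irak1 in the other 2. Its column also carries the animal number of sorted PV WT 2. All 12 PV markers were higher in sorted nuclei (mean log2 2.96), led by Mybpc1 (4.55 ± 0.18) and Pvalb (12.6 ± 2.89 CPM in inputs, 219 ± 13.2 CPM in sorted nuclei, 4.20 ± 0.15), with Mypn, Fam129a and Hes3. Markers of oligodendrocytes (12 of 12, −3.47), their precursors (8 of 8, −4.10), microglia (11 of 11, −3.36), excitatory neurons (10 of 10, −2.86) and astrocytes (11 of 12, −2.52) were lower, and Hpgds, Gcnt1, Plxnb3, Csf3r and Tlr4 fell most among genes at 2 CPM or more. SST markers were lower for 10 of 12. Of 13999 genes, 3518 were higher and 3825 lower in sorted nuclei, and without that input 6580 genes were called.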

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

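The tests below that were chosen after the result was seen are the Irak1 test of labels, the tests for mixed nuclei and retained exons, the depth test for L5 and the test of replicate spread. The KO effect of Grm1 differed between PV and SST by 1.17, that of Chrna4 by 1.07 and that of Galnt14 by 0.87 (log2), among 4 genes whose interaction term passed the threshold. Between excitatory and inhibitory types 12 genes differed, with Irak1 at 0.71, Gsg1l at −1.17, Shh at −1.15, Pygm at −1.06, B3gat1 at −0.92 and Lamb1 at −0.82. Chance was not excluded for either count. Of the 60 splits tried for PV and SST 4 gave as many genes (4 against a highest other of 26), and of the 40 for excitatory and inhibitory types 3 did (12 against 81). For L4 and L5, edgeR called 0 genes with the true labels (200 at an unadjusted p under 0.05, 0 with DESeq2), so that all 60 splits had to give as many and chance was not tested. The highest other split gave 3050, which points to a structure of the samples.

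Chance was excluded for the number of genes called in PV (1 of 35 splits, 109 against a highest other of 74) and SST (1 of 35, 262 against 13), but not in L4 (2 of 35, 23 against 36) or L5 (2 of 35, 3 against 2852). In both L4 and L5 the split that gave more set replicates 1 and 3 against 2 and 4. With the replicate block only 8 splits exist, too few for a share under 0.05 (1 of 8 each, 199 against 30 in L4 and 194 against 0 in L5). Chance was excluded for WT L4 against L5 (1 of 35, 2155 against 37), WT PV against SST (1 of 35, 7043 against 0) and sorted PV against input (1 of 35, 7343 against 1). For the genes called in 2 or more types 1 of 100 splits gave as many, but the margin was narrow (47 against 44) and the 47 include Mecp2 and Irak1. Each of these draws took 1 of the 35 splits of every type, which could be the true one or the L5 split with 2852 genes. The 44 therefore do not show how many genes chance alone gives. The shares above were not corrected for the number of tests. Chance was not excluded for the number of lists called in L4 (23 of 35, 7 against 20), L5 (31 of 35, 4 against 19), PV (28 of 35, 5 against 16) or SST (23 of 35, 8 against 16). Nor was it, by permutation of the labels, for the shifts of PV-SST genes in L4 (12 of 35, camera p = 8.39e-04 against 4.70e-09) and L5 (18 of 35, camera p = 0.189 against 0.00429) or of L4-L5 genes in PV (27 of 35, camera p = 0.373 against 5.46e-06) and SST (14 of 35, camera p = 0.0982 against 0.00125).

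Mecp2 counts stood at the WT level in the 4 libraries labelled L4 KO and in L5 KO 1 and 3. Wrong labels are argued against by Irak1, which was above every WT library of the type in 6 of the 6, and by a score of genes called in both PV and SST (34 higher and 5 lower in L4, 35 and 7 in L5), which was above the WT library of the same number in 6 of 6. WT nuclei mixed into the sort would lower Irak1, yet the lowest Irak1 of L5 KO 1 and 3 was 1.21 times the highest of KO 2 and 4. Transcripts of the targeted allele that still hold counted exons cannot be told apart from other explanations. Mecp2 in sorted L5 KO 3 was 3.46 times that of its input, in the 1 L5 KO pair at hand, against 0.83 in the L5 WT pair. PV, outside this pattern, had 0.848 and 2.36 in KO and 0.841 in WT, in sorted and input libraries of the same animal. The input labelled KO whose column is named as WT gave 0.957 with sorted PV WT 2. L5 KO 1 and 3 also had lower totals (7083299 and 5317786) than KO 2 and 4 (12938097 and 9979344). Their Mecp2 level cannot be told apart from that set of replicates. L5 WT 1 and 3 had Mecp2 at 159 and 161 CPM, and WT 2 and 4 at 180 and 190 CPM. The highest Mecp2 in SST KO was in the library with the lowest total, and that in PV KO in the one with the highest. No cause tied to the totals and no biological explanation was tested.

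Fewer genes were called in L4 (23) and L5 (3) than in SST (262). Lower depth is argued against in L4, since SST thinned to the totals of the L4 libraries gave 181 genes. The mean total of L5 (8842272, SD 2970611) was close to that of SST (8904589, SD 1222218). SST with no library above the L5 mean total gave 254 genes, but this removed few reads and so cannot decide on depth in L5. Whether the uneven totals of the L5 libraries matter was not tested. The spread between replicate numbers is a candidate cause of part of the gap in L4 and L5, as 199 and 194 genes were called with the block. Alone it does not account for all of the gap, since with the block SST had 725. SST was thinned only in the fit without block, so whether spread and lower depth together account for the gap in L4 was not tested. In L5 the count of 194 rests on the numbers of the titles, since with WT 1 and 2 numbered as in the column names 2 genes were called. The column numbering pairs libraries across the 2 sets of L5 replicates. A biological difference between the cell types stays open, untested.

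Genes over 100 kb made up most of the genes higher in KO in PV and SST. A length trend across libraries is argued against as the whole cause, since after each library's trend was removed the share was 63% in PV (51 of 81 higher genes) and 52.5% in SST (63 of 120), against 15.5% and 15.2% of tested genes. As a part of the cause in SST it stays open: the genes higher numbered 185 before, and the 71 no longer called went from a median log2 change of 0.47 (SD 0.21) to 0.37 (SD 0.22). More power from higher counts is argued against too, since the highest share in 10000 draws matched on level was 34.7% in PV and 28.1% in SST. As a hypothesis, found and tested on the same data, the loss of MeCP2 may raise a subset of long genes in these cells.

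Single libraries stood far from the other 3 of their group in 16 of 278 groups of values, where chance gives about 5%. In L5 KO these were chromatin and methylation genes in KO 4 (mean log2 CPM 6.461, others 6.655 to 6.674) and inhibitory (3.025, others 3.535 to 3.602) and SST markers (3.084, others 3.506 to 3.544) in KO 3. In L5 WT 3 they were Irak1 (47.88 CPM, others 35.9 to 36.31) and cadherins (6.15, others 6.351 to 6.367). In PV KO they were heat shock genes in KO 2 (5.812, others 5.489 to 5.502), the neighbours of Mecp2 in KO 3 (5.121, others 4.98 to 4.998), microglia markers in KO 1 (1.748, others 2.292 to 2.332) and reported MeCP2 genes in KO 4 (5.929, others 5.779 to 5.803). In PV WT they were cadherins in WT 2 (6.033, others 5.981 to 5.984), inhibitory markers in WT 3 (7.008, others 7.31 to 7.365) and oligodendrocyte precursor markers in WT 1 (1.656, others 2.445 to 2.544). In SST WT they were Irak1 (59.15 CPM, others 46.66 to 48.55) and activity genes (4.491, others 4.413 to 4.425) in WT 2, and heat shock genes (5.593, others 5.736 to 5.755) and microglia markers (1.345, others 1.972 to 2.096) in WT 1.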

How the results depend on the processing

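Fits to protein-coding genes, to parts of L5 and to sets without ribosomal protein genes were added after the data were seen; the cause of a change was not tested unless stated. Of 112 calls of named genes, some of them of the same gene in several types, 0 reversed, and the call was lost for 0 with the other scaling, DESeq2 or the block, for 3 without the low-count filter, for 54 with limma on log2(TPM + 1) and for 51 with at least 1 library left out. Genes called in L4, L5, PV and SST (23, 3, 109, 262) numbered 178, 21, 446 and 507 without the filter, 58, 50, 259 and 426 with DESeq2, 8, 0, 30 and 86 with limma and 199, 194, 245 and 725 with the block, where L5 gave 2 with WT 1 and 2 numbered as in the column names. At an FDR of 0.1 they were 10 in L5, 218 in PV and 450 in SST. L5 gave 23 within replicates 1 and 3 and 0 within 2 and 4 (507 at an unadjusted p under 0.05, 6 with DESeq2), where fewer libraries were fitted. For PV and SST the interaction count was 7 (FDR 0.1), 9 (no filter), 17 (DESeq2), 2 (limma) and 10 (block), and for excitatory and inhibitory types 29, 6, 51, 4 and 145. Long genes in SST differed by 0.0973 to 0.1293 in 4 of 4 numbers, and the exact sign-flip test with the block gave the smallest p that 4 pairs can give. Genes called in 2 or more types were 163 without the filter, 86 at an FDR of 0.1, 117 with DESeq2 and 211 with the block. In SST, where 1 pair of numbers correlated at only 0.043, PV markers were not called with the block (adjusted p = 0.0752). Lists called in L4 were 13 without the filter and 13 with the block, and with an estimated correlation 0 in each type, where no adjusted p was below 0.05.

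The long gene difference turned to −0.007 in L5 at 50 kb and, in PV, to 0.0219 at 200 kb and 0.0033 when matched on level. Set members over 100 kb were compared with all other tested genes of any length. They gave 0.0909 for L4-L5 genes in PV and 0.101 in SST, both now past an unadjusted 0.05. For PV-SST genes in L4 they gave −0.072, no longer past it. PV-SST genes in L4 gave −0.122 with an estimated correlation, not past the threshold, and protein-coding ones without ribosomal protein genes −0.0901 in L5, now past it. Mecp2 in L4 went from −0.18 (without KO 2) to 0.022 (without KO 4). With 1 library left out the counts were 4 to 19 in L4, 0 to 3 in L5, 64 to 160 in PV, 107 to 277 in SST, 2 to 6 for PV against SST, 9 to 20 for excitatory against inhibitory types and 0 for L4 against L5. The long gene difference was 0.0336 to 0.099 in L4, −0.0405 to 0.0741 in L5, −0.0284 to 0.0308 in PV and 0.0803 to 0.146 in SST. The sets gave −0.0423 to 0.172 (L4-L5 genes in PV), 0.0038 to 0.176 (in SST), −0.167 to −0.0711 (PV-SST genes in L4) and −0.0739 to −0.0095 (in L5). Counts between WT types and of sorted PV against input stayed within 1.5 times.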

Other observations

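The genes named here were chosen after their values were seen, and the shares of shared sign below were computed after the lists of called genes were known. In the fit of L4 with the replicate block, the activity gene Arc (−0.41), the inhibitory marker Gad2 (−0.63), the neuropeptide gene Penk (−0.99) and the serotonin receptor gene Htr2a (−0.42) were lower in KO, and the adrenergic receptor gene Adra1a was higher (0.65). In that of L5, the opioid receptor gene Oprk1 (−1.98), the glutamate receptor genes Grin3a (−0.66) and Grm2 (−0.43) and the serotonin receptor gene Htr1a (−0.55) were lower, and Fkbp5 (0.58) was higher. Of the 31 lists, 17 were called in at least 1 type without the block, 4 only in L4 with it, and 10 in neither, among them the reported MeCP2 genes, the neighbours of Mecp2 and cholesterol synthesis genes.

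Of the genes called in 1 type, the share with the same sign in another was above that of every other split in 8 of 12 ordered pairs of types, with L4 and L5 calls from the fit with the block. Of 106 genes called in PV and tested in SST, 99 (93.4%) had the same sign there, and a split of the SST libraries that ignored the labels reached 93.4% as well, while of those called in SST 93.2% had the same sign in PV, against at most 92.4%. Of 248 genes called in SST and tested in L5, 221 (89.1%) had the same sign, against at most 86.7% for other splits. The share of genes called in the blocked L4 fit with the same sign in PV was 73.9%, and other splits reached 80.6%.

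The L5 inputs had Mecp2 at 61.0 CPM in KO and 194 CPM in WT. The 3 inputs labelled PV KO had 100, 174 and 38.5 CPM, and the 1 PV WT input 201 CPM. The KO input with 174 CPM had Irak1 at 40.4 CPM, beside 114 and 98.9 CPM in the other KO inputs and 41.0 CPM in the WT input, and its deposited column is named as WT. In the PV table, Gapdh was at 16.05 CPM in WT, beside 209, 190 and 263 CPM in L4, L5 and SST.

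The authors' deposited comparison tables hold 39 genes higher and 26 lower in L4 KO at an adjusted p under 0.05, 107 and 84 in L5, 166 and 124 in PV and 293 and 132 in SST. Of these, 20, 3, 97 and 217 were also called here without the block, and 65, 152, 204 and 410 with it.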
